A study of Arabidopsis thaliana with 2 samples.

How the data were processed

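Total RNA from shoots of 7-day-old wild-type (Col-0) and wn1 seedlings was extracted with a silica column kit and sequenced on libraries made by an Illumina protocol, per the labels' protocols. The series design text, which speaks of mRNA, adds that a sequencing company processed the raw data again. Whether polyadenylated RNA was selected, the strand setting, the read length and the hour of harvest are not given in the sources used here. There were 2 samples, 1 of each genotype, with no replicates.

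The authors deposited a table of FPKM with 1 row per annotated gene. Bowtie and the build TAIR10 are named in the submitters' processing notes, and the read counter, the versions and any filters are not given in the sources used here. Of the 33565 rows, 27371 were typed as protein-coding and 3911 carried no type. The FPKM columns were matched to samples by their names, WT for wild type and WN for wn1. Both names end in R, a suffix whose meaning is not given in the sources used here. A further 2 columns of per-sample values named other material and were not used here. No scaling between the samples beyond FPKM is stated. Genes whose transcripts resemble each other, such as Rubisco small subunit genes and copies in the plastid inverted repeat, share reads, and how the authors divided them is not given in the sources used here. An FPKM of 0 can be a failed estimate for very short genes, so genes listed at 0 in a library are given by both values with no fold. A very high FPKM of such a gene may be as unreliable. Without a stated strand, reads of overlapping or antisense genes cannot be separated, which bears on the crowded plastid genome in particular. No coordinates are printed, because the reference annotation used here (TAIR10.1) differs from the build of the table, and it served only for names, transcript lengths, coding lengths and gene order.

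From the FPKM, log2((wn1 + 1)/(wild type + 1)) was computed, with a pseudocount of 1. Genes with a mean FPKM of at least 1 over the 2 libraries were kept, 18788 in all, of which 18420 (98.0%) were protein-coding. Genes were counted as higher or lower at 2-fold or more. With 1 library per genotype these counts describe the libraries and carry no error rate. For 35 gene lists with 530 genes, all found in the table, the median log2 difference of the measured members was set against 10000 random lists of the same size, matched in 20 bins of mean FPKM. A list was said to stand apart when its median lay in the lowest or highest 2.5% of the random lists, and a list needed 3 measured members, which left 34. These lists, the comparison, the size rules and most alternatives were fixed before the data were examined. The genes named were the 12 with the largest and the 12 with the smallest log2 difference among genes with a mean FPKM of at least 5, in each list the 3 members with the largest absolute difference and the member with the highest mean FPKM, and the reference genes. Other members named as examples (RPOA, RPOB, CLPP1, RPS14, RPL23.1, PSBA, RBCL, PSBB, PSBH, ATPA, ATPB, ATPH, NDHA, NDHB.1, NDHB.2, NDHC, NDHF, NDHI, FSD3, GLK2, PIF3, PIF4, CASP1 and FRO2) and the ribosomal RNA rows were chosen after their values were seen. The text names fewer genes than the rule selects, and genes not reported here are still counted in their lists. A further 5 lists with 60 genes were written after the values were seen and are used only in the closing section.

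Depth was read from the values. Among 994 genes with 1 transcript and both values between 0 and 0.3 FPKM, 84.8% of the ratios of wn1 to wild type lay within 0.5% of 0.822 times a ratio of whole numbers up to 6, against 1.41% for a step 3 percent larger. This gives a depth of wn1 1.22 times that of wild type. With reference transcript lengths of at least 1000 bases and values up to 0.15 FPKM, the depth was estimated at about 12500000 fragments for wild type and 15500000 fragments for wn1. These are estimates, and an interval made from them covers counting error only.

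The steps were tested on simulated data built from the mean FPKM of the libraries with an assumed random spread, for the comparison of wn1 with wild type over 18787 genes. The spread was assumed, so the figures check the steps and give no error rate for these plants. Of 100 genes simulated at 2-fold, 42 passed the 2-fold rule, as did all 100 simulated at 4-fold and 1 of the remaining 18587 genes. A list of 20 genes raised by 0.5 log2 units lay above all 10000 random lists, and 13 of 200 lists of that size drawn at random stood apart.

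Alternatives were a pseudocount of 0.1, a mean FPKM of at least 5, no filter on low values, centring on the median of all genes, dividing each column by its own sum over all genes (rescaling to a common total), rescaling without organelle genes, and a threshold of 4-fold. Added after the data were seen were protein-coding genes only with rescaling, and leaving out genes listed at 0 in a library. With no replicates, a value was counted as moved when it differed by more than 1.5-fold, and the median of a list that stood apart as reversed when its sign changed. The software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.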

Results

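RNA sequencing compared shoots of wn1, an Arabidopsis thaliana mutant that the labels describe as whitening, with shoots of its wild-type background Col-0. Seedlings were 7 days old and had grown on solid medium at 22 °C under 16 h of light and 8 h of dark, and the tissue label names shoot and cotyledon. There was 1 library per genotype, so no difference had a replicate check, no test was possible and no p-value is given. Differences are log2 differences of FPKM + 1 (fragments per kilobase of transcript, scaled to the mapped total), wn1 minus wild type, which understate the difference for genes of low FPKM. The depth was not given with the values. The steps between low FPKM values gave a depth of wn1 1.22 times that of wild type, and transcript lengths gave estimates of 12500000 fragments for wild type and 15500000 fragments for wn1. At that depth 5 FPKM on a transcript of 1 kb stood for about 62.4 fragments in wild type and 77.6 in wn1.

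The comparison asked which transcripts differ between the whitening mutant and wild type. In wn1, plastid-encoded protein-coding genes for transcription, translation and housekeeping mostly had higher FPKM than in wild type, with a list median log2 difference of 1.68. The plastid ribosomal RNA rows ATCG00950 and ATCG00920, outside that list, had 594 and 391 FPKM in wild type against 65.8 and 50.7 in wn1. Plastid-encoded photosynthesis genes were mixed, with a median of -0.62 and 13 of 22 measured members below 0. Plastid-encoded protein-coding rows had a median of only 6.82 FPKM in wild type, and how far the libraries captured unpolyadenylated plastid RNA is not given. Nuclear photosystem subunits were modestly lower, with a median of -0.49. Nuclear genes for the plastid transcription machinery were higher, with a median of 0.47. This direction reversed when each column was divided by its own sum, a scaling set in wn1 mostly by 1 transfer RNA row. Relative to other genes the list still stood apart after that division. PTAC10 was the 1 measured member of that machinery with lower FPKM in wn1. The regulators GLK1 and GLK2 of chloroplast development and the jasmonate synthesis gene LOX2 were also lower in wn1, and the starvation marker ASN1 was higher. The list of phenylpropanoid, flavonoid and anthocyanin genes had a median of -0.57, with 7 of 18 members at least 2-fold lower and 1 at least 2-fold higher. Heat shock genes had a median of -0.85 with 3 of 8 at least 2-fold lower, and seed genes one of -1.30 with 7 of 12.

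Of 33565 annotated genes, 18788 had a mean FPKM of at least 1, and their log2 differences had a median of 0.03, quartiles of -0.25 and 0.31 and a standard deviation of 0.63. Across these genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) between the libraries was 0.943. At least 2-fold higher in wn1 were 690 genes and at least 2-fold lower were 685, together 7.32% of the genes. At least 4-fold higher were 72 and at least 4-fold lower were 128. The balance of higher and lower genes depended on which rows set the scale. Rescaled without organelle genes, 706 were higher and 697 lower, so 50.3% were higher against 50.2% as deposited. With protein-coding genes alone rescaled to a common total, 926 were higher and 566 lower. The median of all genes then shifted to 0.14, and 62.1% were higher. That total includes PSBM, at 67475 FPKM in wild type and listed at 0 in wn1. Dividing each column by its own sum gave 80 higher and 6338 lower, 1.25% higher, with a median of -0.84. That last scaling followed 1 row, the plastid transfer RNA gene ATCG00010, which was listed at 0 in wild type and at 1005100 FPKM in wn1, 54.1% of all FPKM in that library, while 36 of the 37 plastid transfer RNA rows were listed at 0 in both. Dividing by column sums lowered nearly every gene alike, so a modest positive median turned negative by construction. Of the 20 lists that stood apart, 19 still did after that division. Rescaling without organelle genes kept all 31 lists with a value within 1.5-fold of the reported median. The values below are FPKM as deposited. Among 34 gene lists with a value, 12 lay below and 8 above the central 95% of expression-matched random lists. These positions describe the libraries and are no test, since genes of a list can vary together between any plants or harvest hours.

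**Figure D1:**
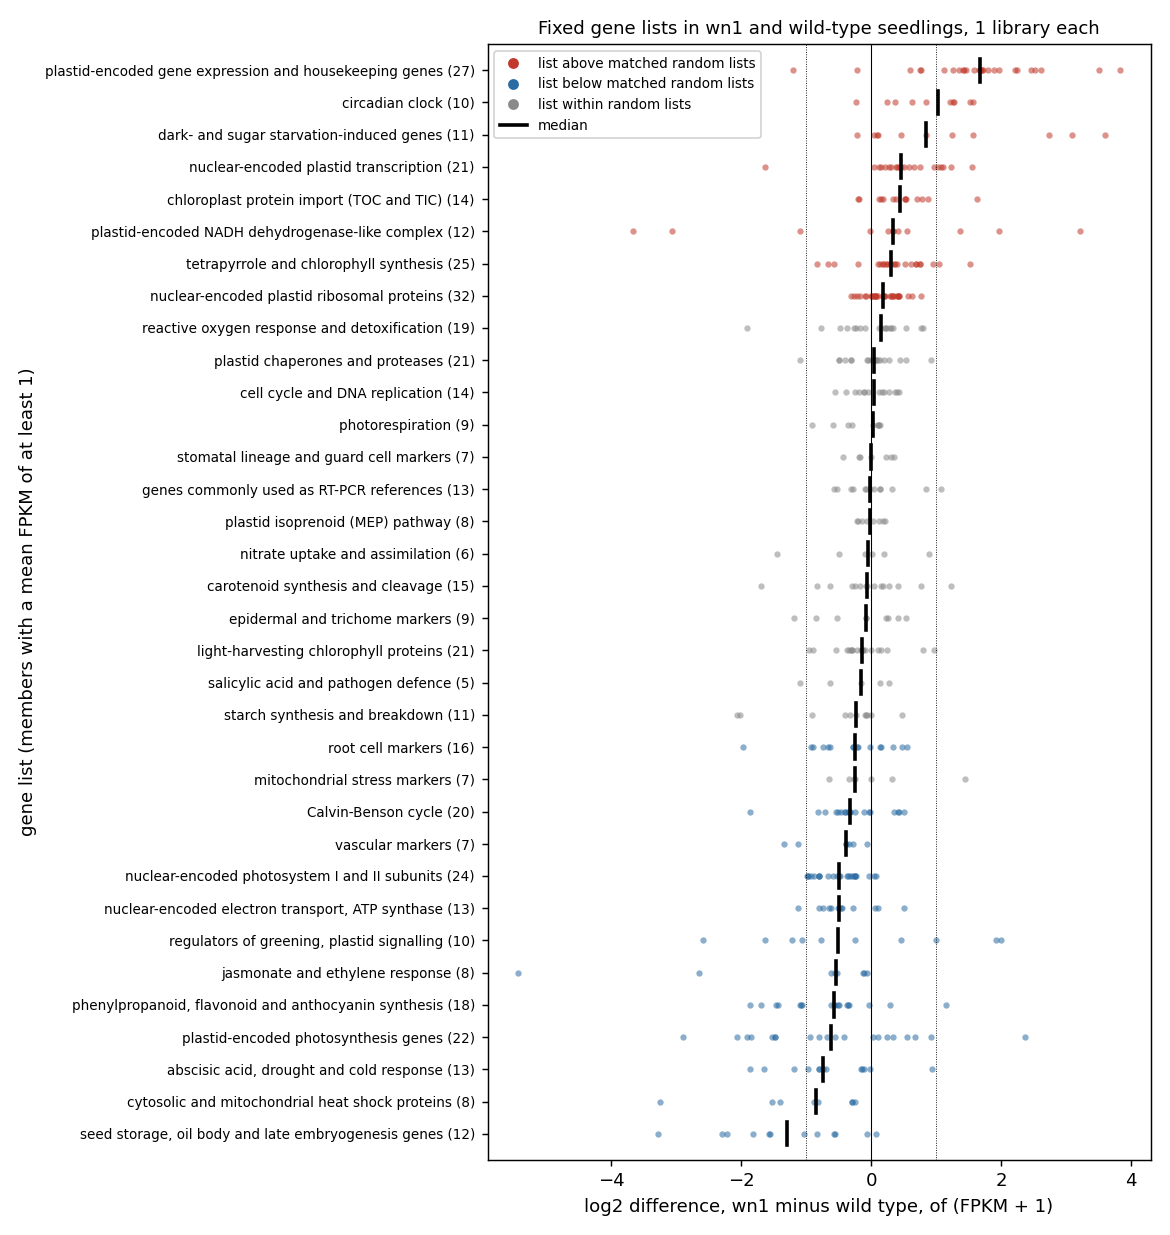
Log2 differences of FPKM + 1 (horizontal axis, wn1 minus wild type) for the members of 34 gene lists (vertical axis), 1 library per genotype. Points are genes with a mean FPKM of at least 1 and FPKM above 0 in both libraries, black bars are medians over all measured members, and dotted lines mark 2-fold. Red lists lay above, blue lists below and grey lists within matched random lists; the medians run from -1.30 for seed genes to 1.68 for plastid gene expression genes, and dividing by column sums turns every red list below 0 except plastid gene expression and clock genes, and the grey lists of reactive oxygen, chaperone, cell cycle and photorespiration genes too.

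Plastid-encoded protein-coding genes for gene expression and housekeeping stood highest of all lists. Of 27 measured members, 22 were at least 2-fold higher in wn1, 1 was at least 2-fold lower and 4 lay within 2-fold, and the median lay above all 10000 random lists. RPOA (ATCG00740), the alpha subunit of the plastid-encoded RNA polymerase, had 9.53 FPKM in wild type and 57.3 in wn1, a log2 difference of 2.47, and RPOB (ATCG00190) had 5.95 and 17.8. CLPP1 (ATCG00670), a subunit of the plastid Clp protease, had 23.9 and 142 FPKM. RPS15 (ATCG01120), a plastid ribosomal protein gene, differed by 3.84 with 1.06 and 28.5 FPKM, and YCF1.2 (ATCG01130) by 3.51 with 9.15 and 115 FPKM. The member at least 2-fold lower was RPS14 (ATCG00330), at 34.7 and 14.4 FPKM, and RPL23.1 (ATCG00840) had 39.1 and 33.7. Highest in mean FPKM was RPL16, at 440 FPKM in wild type and 964 in wn1.

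Plastid-encoded photosynthesis genes had a lower median but were mixed. Of 22 measured members, 13 lay below 0 and 9 above, 8 were at least 2-fold lower in wn1, 2 at least 2-fold higher and 12 within 2-fold, and the median lay below all 10000 random lists. PSBA (ATCG00020), which encodes the D1 protein of photosystem II, had 18.9 FPKM in wild type and 4.50 in wn1, a log2 difference of -1.86. RBCL (ATCG00490), the large subunit of Rubisco, had 69.3 and 24.2, and PSBB (ATCG00680) had 17.9 and 4.01. PSBE (ATCG00580) differed by -2.89, with 30.2 and 3.20 FPKM. The ATP synthase genes ATPA (ATCG00120) and ATPH (ATCG00140) had 15.6 and 21.6 FPKM in wild type against 30.7 and 35.1 in wn1, while ATPB (ATCG00480) had 152 and 78.4. PSAC (ATCG01060), a photosystem I subunit, went against the median of its list with 1.44 and 11.7 FPKM, a difference of 2.38. The other member counted as higher was PSBH, listed at 0 in wild type and at 3.62 FPKM in wn1. PSBM (ATCG00220) had 67475 FPKM in wild type and was listed at 0 in wn1, and a further 11 of the 33 listed genes were listed at 0 in both libraries, so an entry of 0 for these short genes can be a failed estimate. The value of 67475 stood far above the median of 6.82 FPKM of plastid-encoded protein-coding rows in wild type, so it may be unreliable too.

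Genes of the plastid NADH dehydrogenase-like complex split. Of 12 measured members 3 were at least 2-fold higher and 3 at least 2-fold lower, and the median of 0.34 lay above 9848 of the random lists. That median was the value of NDHB.1 and NDHB.2, which were both listed at 2.02 FPKM in wild type and 2.81 in wn1. It became -0.34 both among genes with a mean FPKM of at least 5, where NDHB.1 and NDHB.2 drop out, and after division by column sums. NDHK (ATCG00430) had 158 FPKM in wild type and 11.6 in wn1, a difference of -3.66, and NDHJ (ATCG00420) differed by -3.06. NDHH (ATCG01110) had 2.499 and 31.4 FPKM, a difference of 3.21. The 3 members at least 2-fold lower, NDHJ, NDHK and NDHC, have consecutive identifiers (ATCG00420 to ATCG00440). The 3 at least 2-fold higher, NDHF, NDHA and NDHH, lie between ATCG01010 and ATCG01110. In that stretch NDHI was at -0.01 and the other members of the list were above 0. The plastid ribosomal RNA rows ATCG00950 and ATCG00920, chosen after their values were seen, had 594 and 391 FPKM in wild type against 65.8 and 50.7 in wn1, and their copies in the inverted repeat had nearly identical values, since such copies share reads.

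The nuclear genes whose products transcribe plastid genes were higher in wn1 in 20 of 21 cases, with 5 at least 2-fold higher and a median of 0.47 above all 10000 random lists, a direction that reversed after division by column sums. These comprise sigma factors, phage-type RNA polymerases and proteins associated with the plastid-encoded polymerase. PTAC6 (AT1G21600) had 25.3 FPKM in wild type and 76.3 in wn1, a difference of 1.55, PTAC3 (AT3G04260) had 18.3 and 44.2, and the superoxide dismutase FSD3 (AT5G23310) had 11.9 and 26.9. PTAC7 (AT5G24314), the highest member in mean FPKM, had 160 and 210. PTAC10 (AT3G48500), a component of the plastid transcriptionally active chromosome, was the exception at 14.1 FPKM in wild type and 3.87 in wn1, a difference of -1.64. Nuclear plastid ribosomal protein genes were slightly higher, with a median of 0.19 that also reversed after division by column sums. All 32 lay within 2-fold, the median lay above 9867 random lists, and RPL29 differed most with 472 and 807 FPKM. Genes for the chloroplast protein import complexes had a median of 0.45, above 9976 random lists and likewise reversed by that scaling, with 12 of 14 members above 0. TOC33 (AT1G02280), a receptor of the outer envelope, had 45.4 FPKM in wild type and 143 in wn1, and TOC159 (AT4G02510) had 90.8 and 168. Plastid chaperones and proteases did not stand apart, with a median of 0.05 that was -0.95 after division by column sums. Among them CLPB3 had 166 and 77.1 FPKM, while CPN60B had 240 and 458.

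Nuclear genes for photosynthesis differed by less than 2-fold in nearly all cases, and their lists other than the light-harvesting proteins lay below random lists. For photosystem I and II subunits, all 24 measured members lay within 2-fold, 22 were below 0, and the median of -0.49 lay below 9999 of the random lists. PSBY (AT1G67740) had 2947 FPKM in wild type and 1494 in wn1, and PSAG (AT1G55670) had 3517 and 1803. Electron transport and chloroplast ATP synthase genes had a median of -0.49, below 9964 random lists, with ATPD (AT4G09650) at 1646 and 756 FPKM. Calvin-Benson cycle genes had a median of -0.33, below 9936 random lists. There the small Rubisco subunit gene RBCS2B (AT5G38420) had 6909 and 1903 FPKM, and RBCS1A (AT1G67090) had 19784 and 13647. These genes have near-identical relatives that share reads, so the division among them is uncertain. Light-harvesting chlorophyll protein genes did not stand apart, with all 21 within 2-fold and a median of -0.14. LHCB2.2 had 2493 FPKM in wild type and 1287 in wn1, while LHCB1.4 had 1540 and 3006, with the same uncertainty between relatives.

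Tetrapyrrole and chlorophyll synthesis genes were slightly higher in wn1, with a median of 0.31 above 9933 random lists, a direction that reversed after division by column sums. Of 25 members 21 lay above 0, but 23 lay within 2-fold and 2 were at least 2-fold higher. HEMA1 (AT1G58290), the glutamyl-tRNA reductase at the start of the pathway, had 172 FPKM in wild type and 494 in wn1, a difference of 1.52. HEME1 (AT3G14930) had 63.2 and 132. CRD1 (AT3G56940), 1 of the 4 members below 0, had 1597 and 1072. Carotenoid synthesis did not stand apart with a median of -0.07, though BCH2 (AT5G52570), a beta-carotene hydroxylase, had 176 and 53.8 FPKM. In the same list NPQ1 (AT1G08550) was higher in wn1, with 16.3 and 39.7 FPKM. The plastid isoprenoid pathway had a median of -0.02, and all 8 members lay within 2-fold.

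Transcriptional regulators of greening and plastid signalling differed in both directions. Of 10 measured members, 3 were at least 2-fold higher and 4 at least 2-fold lower, and the median of -0.51 lay below 9980 random lists. GLK1 (AT2G20570) and GLK2 (AT5G44190), which activate nuclear photosynthesis genes, had 72.8 and 147 FPKM in wild type against 11.3 and 46.9 in wn1. The light-signalling factors PIF3 (AT1G09530) and PIF4 (AT2G43010) had 46.6 and 66.0 FPKM against 19.6 and 31.0. HY5 (AT5G11260), which promotes photomorphogenesis, had 26.5 FPKM in wild type and 109 in wn1, a difference of 1.99. The GATA factor CGA1 (AT4G26150) had 8.57 and 35.2. GUN1 (AT2G31400), a mediator of plastid-to-nucleus signalling, had 160 and 220.0.

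**Figure D2:**
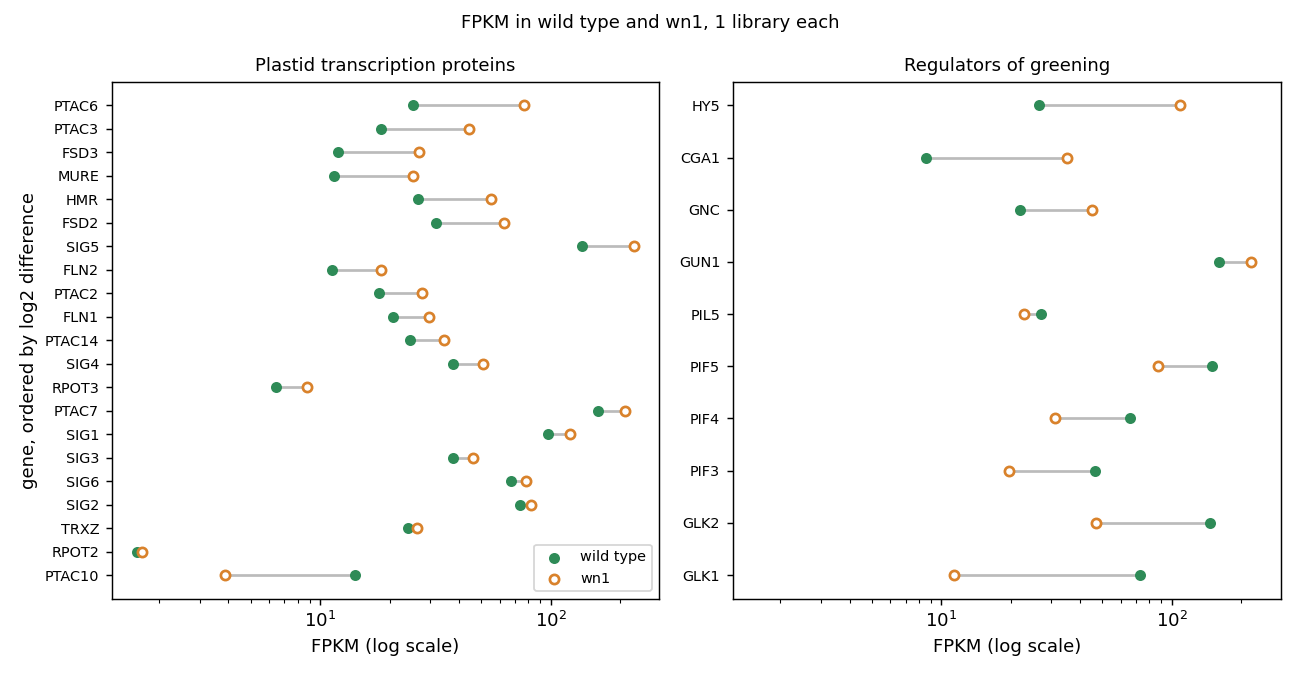
FPKM on a logarithmic horizontal axis in wild type (filled circles) and wn1 (open circles), 1 library each, for nuclear genes of plastid transcription (left) and regulators of greening (right), ordered by log2 difference along the vertical axis. In the left panel PTAC10 has lower FPKM in wn1 (14.1 and 3.87) and the other 20 genes have higher FPKM, a direction that as a list reverses after division by column sums; on the right GLK1 (72.8 and 11.3) and HY5 (26.5 and 109) lie at opposite ends.

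Carbon and nitrogen genes differed by list. Dark- and sugar starvation-induced genes had a median of 0.84, above all 10000 random lists and reversed after division by column sums, and 5 of 11 were at least 2-fold higher. ASN1 (AT3G47340), an asparagine synthetase induced in darkness, had 21.0 FPKM in wild type and 267 in wn1, a difference of 3.60. BCAT-2 (AT1G10070), a branched-chain aminotransferase, had 4.03 and 41.8, and SEN1 (AT4G35770) had 53.4 and 361. Starch genes did not stand apart, with a median of -0.23 above 500 of the random lists. Among them GBSS1 (AT1G32900), the granule-bound starch synthase, had 369 and 87.4 FPKM, and APL3 (AT4G39210), a large subunit of ADP-glucose pyrophosphorylase, had 34.9 and 7.84. Photorespiration, with a median of 0.03 that was -0.97 after division by column sums, and nitrate assimilation, with a median of -0.04, did not stand apart. The nitrate transporter gene NRT1.1 (AT1G12110) had 52.5 FPKM in wild type and 18.6 in wn1, while NIA1 (AT1G77760) had 145 and 269.

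Stress, hormone and pigment lists were mostly lower in wn1. Phenylpropanoid, flavonoid and anthocyanin genes had a median of -0.57, with 7 of 18 at least 2-fold lower and 1 at least 2-fold higher. PAP1 (AT1G56650), a MYB activator of anthocyanin synthesis, had 13.5 FPKM in wild type and 2.99 in wn1, and DFR (AT5G42800) had 43.5 and 12.7. All 8 measured heat shock protein genes lay below 0, with a median of -0.85, and HSP70 (AT3G12580) had 315 and 118 FPKM. The abscisic acid, drought and cold list had a median of -0.75, with 12 of 13 members below 0. NCED3 (AT3G14440), which makes the abscisic acid precursor, had 69.5 and 18.3. Each of these 3 lists lay below all 10000 random lists. Jasmonate and ethylene response genes had a median of -0.54, below 9986 random lists, with all 8 measured members below 0. Only 2 were at least 2-fold lower, the jasmonate synthesis genes LOX2 and AOS, and the other 6 lay within 2-fold. LOX2 (AT3G45140), a plastid lipoxygenase of jasmonate synthesis, had 98.3 FPKM in wild type and 1.29 in wn1, a difference of -5.44, and AOS (AT5G42650) had 47.0 and 6.70. The remaining lists of this kind did not stand apart: reactive oxygen response with a median of 0.16 that was -0.80 after division by column sums, salicylic acid and pathogen defence with -0.16, and mitochondrial stress markers with -0.25.

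Markers of other cell types and stages were measured alongside. Seed storage, oil body and late embryogenesis genes were lower in wn1, with a median of -1.30 below all 10000 random lists and 7 of 12 at least 2-fold lower, though with no filter on low values the median was -0.70. CRC (AT4G28520) had 24.3 FPKM in wild type and 1.60 in wn1, and CRA1 (AT5G44120) had 42.3 and 7.81. Root markers had a median of -0.24, below 9840 random lists. This list no longer stood apart among genes with a mean FPKM of at least 5, where the iron uptake genes IRT1 and FRO2 drop out. Root markers were present in both libraries labelled shoot, and whether the samples held root tissue is not given in the sources used here: PYK10 (AT3G09260) had 1521 and 2225 FPKM, LRX1 (AT1G12040), a root hair gene, had 45.2 and 23.9, and CASP1 (AT2G36100), of the root endodermis, had 25.1 and 20.6. Vascular markers had a median of -0.38, below 9812 random lists, and no longer stood apart with a pseudocount of 0.1 or after division by column sums. The phloem genes SUC2 (AT1G22710) and APL (AT1G79430) had 79.6 and 10.1 FPKM in wild type against 35.8 and 3.37 in wn1. Guard cell markers with a median of 0.00, epidermal markers with -0.07 and cell cycle genes with 0.04 did not stand apart, and the last was -0.68 after division by column sums. Of the shoot meristem markers 2 were measured, STM at 1.65 and 2.15 FPKM and KNAT1 at 15.1 and 15.7.

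Circadian clock genes were higher in wn1, with a median of 1.03 above all 10000 random lists and 5 of 10 at least 2-fold higher, but after division by column sums the median was 0.077. LHY (AT1G01060), a morning gene, had 222 FPKM in wild type and 532 in wn1, PRR9 (AT2G46790) had 15.5 and 48.3, and GI (AT1G22770) had 8.77 and 22.8. The hour of harvest is not given in the sources used here, and clock genes differ by hour. Genes often used as RT-PCR references had a median of -0.01 and did not stand apart. ACT8 (AT1G49240), at 176 and 373 FPKM, and ACT2 (AT3G18780), at 486 and 876, were higher in wn1. After division by column sums their differences of 1.07 and 0.85 became 0.07 and -0.16, while the median of the reference list became -0.98. Rescaled without organelle genes, the differences of ACT8 and ACT2 were 1.08 and 0.86.

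Among genes with a mean FPKM of at least 5, those with the largest differences and FPKM above 0 in both libraries included iron and sulfur genes. BHLH100 (AT2G41240), a transcription factor induced by iron deficiency, had 94.2 FPKM in wild type and 0.209 in wn1, a difference of -6.30. Its relatives BHLH38 (AT3G56970) and BHLH39 (AT3G56980) had 57.0 and 43.7 FPKM against 0.770 and 0.427. The sulfur deficiency markers SDI1 (AT5G48850) and LSU1 (AT3G49580) had 46.8 and 54.9 FPKM against 1.19 and 2.01, and the beta-glucosidase gene BGLU28 (AT2G44460) had 26.7 and 0.155. At the upper end stood RPS15, AT5G09670 with 0.538 and 18.6 FPKM, ASN1, YCF1.2 and AT2G33830 with 11.1 and 113. Besides ATCG00010, 5 of the 12 highest genes were listed at 0 in wild type, among them AT2G01021 at 15801 FPKM and AT2G40205 at 3645 FPKM in wn1, and 4 of the 12 lowest were listed at 0 in wn1, among them PSBM. Plastid-encoded genes made up 7.92% of summed FPKM in wild type and 54.4% in wn1, an order that turned to 7.79% and 0.732% over protein-coding genes. The shares of 7.92% and 7.79% in wild type were mostly PSBM, at 67475 FPKM there and listed at 0 in wn1. The share of 54.4% in wn1 was mostly ATCG00010. Because the values of PSBM and ATCG00010 may be unreliable, the shares that rest on them cannot be read as abundances. When genes listed at 0 in either library were left out, the plastid shares were 0.657% and 0.761%. Mitochondria-encoded genes made up 0.0418% in wild type and 0.0365% in wn1, an order that turned to 0.0148% and 0.0225% over protein-coding genes and to 0.0446% and 0.0809% without genes listed at 0.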

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

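No paired analysis was possible because each genotype had 1 library. The alternatives restricted to protein-coding genes, those leaving out genes listed at 0, and all values of the 5 later lists were chosen after the data were seen. Of 269 medians of the earlier lists under alternatives, 233 stayed within 1.5-fold, 29 moved further and 7, of lists that stood apart, reversed their sign. Of those 36, 34 came from dividing each column by its own sum, whose wn1 value is mostly the row ATCG00010, so that scaling moved nearly every gene the same way by its construction. Without organelle genes the 3 plastid-encoded lists have no value. Estimated depth limits genes near 1 FPKM, which rest on about 12.5 fragments per kilobase in wild type and 15.5 in wn1.

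After division by column sums the lists that had stood apart and changed sign were chloroplast import at -0.45, starvation at -0.14, plastid ribosomal proteins at -0.82, plastid transcription at -0.47, the plastid NADH dehydrogenase-like complex at -0.34 and chlorophyll synthesis at -0.65. With a mean FPKM of at least 5 the NADH dehydrogenase-like list was at -0.34 and reversed too, since members of lower FPKM, NDHB.1 and NDHB.2 among them, dropped out. This list and the root list no longer stood apart under that filter. With no filter the seed list moved to -0.70, since silent members enter. Vascular markers no longer stood apart with a pseudocount of 0.1 or after division by column sums. Lists that had not stood apart also changed sign under that division: reactive oxygen, chaperones and proteases, cell cycle, photorespiration and ferritins. Relative to other genes, 19 of the 20 lists that stood apart still did after that division.

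The other medians moved by that division were, among photosynthesis and plastid lists, Calvin-Benson cycle -1.34, light-harvesting proteins -1.15, electron transport -1.50, photosystem subunits -1.49, plastid-encoded photosynthesis -1.55, plastid gene expression 0.71, chaperones and proteases -0.95, isoprenoids -1.02, carotenoids -1.03, greening regulators -1.48 and photorespiration -0.97. Among stress, hormone and metabolic lists they were abscisic acid and cold -1.75, heat shock -1.72, jasmonate and ethylene -1.43, mitochondrial stress -0.96, nitrate -1.05, flavonoids -1.57, reactive oxygen -0.80, salicylic acid -1.01 and starch -1.19. Among cell type and other lists they were cell cycle -0.68, clock 0.077, epidermis -0.90, reference genes -0.98, root -1.16, seed -2.09, guard cell -0.72 and vascular -1.25. The later lists came to 0.18 for amino acid breakdown, -0.43 for ferritins, -2.76 for iron, -1.41 for jasmonate synthesis and -3.41 for sulfur.

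The count of higher genes was 80 after that division and 72 at a 4-fold threshold, and that of lower genes 6338 and 128. Under the other alternatives both counts lay within 1.5-fold of the reported ones. The plastid share over protein-coding genes was 7.79% in wild type and 0.732% in wn1, so its order turned. That wild-type share was mostly 1 row, PSBM, listed at 0 in wn1. Without genes listed at 0 the plastid share was 0.657% in wild type and 0.761% in wn1. The mitochondrial share over protein-coding genes was 0.0148% in wild type and 0.0225% in wn1, and without genes listed at 0 it was 0.0446% and 0.0809%, so its order turned under both. Of 989 values of 144 named genes under the alternatives other than division by column sums, 977 stayed within 1.5-fold and 12 moved, all with a pseudocount of 0.1.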

Other observations

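The lists of iron, ferritin, sulfur, jasmonate synthesis and amino acid breakdown genes, and the tests of explanations in this part, were chosen after the values were seen, while the plastid lists were fixed earlier. Iron deficiency response genes were lower in wn1 as a group. Of 17 genes 15 were at least 2-fold lower and 16 below 0, with a median log2 difference of -1.98 that lay below all 10000 random lists. Because the list was written after the extremes had been looked at, it was repeated without them. Of the 10 members outside the earlier lists and outside the 40 highest and 40 lowest genes, 9 were at least 2-fold lower and the median was -1.54. The whole list was written after the values were seen, so this repeat is no independent check, nor are those of the later lists below. The peptide gene IMA2 (AT1G47395) had 145 FPKM in wild type and 18.4 in wn1, the transporter gene OPT3 (AT4G16370) had 189 and 62.7, and the regulator BTS (AT3G18290) had 106 and 30.0. Several members are best known from roots. Root markers were present in both libraries and were slightly lower in wn1 as a list, with a median of -0.24 and 11 of 16 members below 0. IRT1 and FRO2 belong to both the root and the iron list, so the root list is no separate gauge of root content. FIT (AT2G28160), the root regulator of iron uptake, was the member above 0, with 1.43 and 2.18 FPKM. The 3 measured ferritin genes, which store iron, had a median of 0.57 above 9537 random lists and did not stand apart, and the median turned to -0.43 after division by column sums, with FER1 (AT5G01600) at 136 and 202. Sulfur deficiency and sulfate assimilation genes were lower too. All 15 were below 0 and 11 at least 2-fold lower, with a median of -2.46. The 10 members outside the earlier lists and those extremes had a median of -1.70. APR1 (AT4G04610), an adenosine phosphosulfate reductase, had 116 and 9.10 FPKM, APR3 (AT4G21990) had 103 and 17.8, and LSU2 (AT5G24660) had 27.3 and 2.52.

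Jasmonate synthesis genes were below 0 in all 11 measured cases, with 5 at least 2-fold lower and a median of -0.54 below 9998 random lists. The 7 measured members outside the earlier lists and the extremes had a median of -0.48, with 2 at least 2-fold lower. With a mean FPKM of at least 5 this remainder held 6 genes, had a median of -0.32 and no longer stood apart. AOC2 (AT3G25770), an allene oxide cyclase, had 47.1 FPKM in wild type and 1.89 in wn1, and AOC1 (AT3G25760) had 21.2 and 3.08, while OPR3 (AT2G06050) had 11.2 and 10.2. Genes that break down branched-chain amino acids, lysine and proline were above 0 in all 13 cases, with 7 at least 2-fold higher and a median of 1.13 above all 10000 random lists. The median was 0.18 after division by column sums. The 10 members outside the earlier lists and the extremes had a median of 0.69, which turned to -0.27 after that division. ERD5 (AT3G30775), a proline dehydrogenase, had 21.8 and 118 FPKM, DIN4 (AT3G13450) had 7.19 and 27.9, and IVD (AT3G45300), isovaleryl-CoA dehydrogenase, had 18.3 and 52.0.

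Within the plastid genome, gene expression genes had a higher median difference than photosynthesis genes, of which 9 of 22 lay above 0, with a difference of the list medians of 2.301. The gene expression list holds protein-coding genes only, and the plastid ribosomal RNA rows were lower in wn1. A factor common to all genes would move both lists alike, and the lower quartile of the first, 1.31, lay above the upper quartile of the second, 0.31. Unstable FPKM of short genes was weighed on genes with a coding length of at least 500 bases, where the difference was 2.31 over 12 and 13 genes. No biological explanation was tested, and the genotype stays open as one. The 7 photosynthesis genes next to a gene expression gene had a median of -1.48 and ran from -2.07 at PSAJ to 0.56 at ATPI. This does not decide whether reads spread between neighbours. The NADH dehydrogenase-like genes were left out of it. NDHH, RPS15 and YCF1.2, at 3.21, 3.84 and 3.51, have consecutive identifiers and the largest positive differences of the plastid genes drawn. PSAC, at 2.38, lies in the same stretch. Gene expression genes elsewhere, such as RPOA at 2.47 and CLPP1 at 2.53, were higher too, while RPS14 was lower. Position and list membership were not separated. Strand effects and the capture of unpolyadenylated plastid RNA were not tested. Plastid-encoded protein-coding rows had a median of 6.82 FPKM in wild type, and the values of both lists may depend on that capture.

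PTAC10 was lower in wn1 while the other 20 genes of plastid transcription were above 0, with the lowest of them at 0.051, although the median of the whole list was -0.47 and PTAC10 at -2.41 after division by column sums. Counting noise was weighed from estimated fragments of 423 in wild type and 144 in wn1, whose log2 ratio of FPKM was -1.87 with an exact binomial 95% interval from -2.15 to -1.59, covering counting error only. PTAC10 ranked at place 170 from the lowest among 13694 genes with a mean FPKM of at least 5, so many genes lay lower. The labels do not name the gene mutated in wn1, and 1 of the columns not used here carries the name PTAC10. No biological explanation was tested, and variation between plants stays open, since there were no replicates.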
